A study of Mus musculus with 18 samples.

How the data were processed

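The libraries were made from naive CD4 T cells of Id3-KO and WT mice, stimulated with beads against CD3 and CD28 in IMDM medium with serum, IL2, IL12 and an antibody to IL4, per the labels' protocols. RNA was purified with RNeasy columns, polyadenylated RNA was selected, and stranded libraries were prepared with the NEBNext Ultra II Directional kit, per the labels' protocols. The labels give 6 groups of 3 libraries, KO and WT in sets 3, 5 and 6. They do not state whether the replicates came from different mice, so p-values measure the spread between these samples.

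The authors used Salmon 1.9.0, edgeR, limma and the GRCm39 assembly, per the submitters' processing notes, which do not say what each was used for. The values of the main table are on a log2 scale of counts, per the file headers and the range of the deposited values. The normalization is not given in the sources used here. Within each group 97.0 to 98.4% of the sorted values were identical and between groups they were not, so the deposited values had been equalized within groups; this compresses the spread within groups, and p-values may be smaller for it. The depth per library cannot be recovered; the lowest tied value of a library, 1.00 to 1.11, was held by 149 to 350 genes, and a gene at that value in all libraries of a compared group is described by its levels, named without a fold, or given a value marked as resting on it.

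A second deposited table holds 6 contrasts of the authors with log2 fold changes, a test score (moderated t), p-values and adjusted p-values, per the file headers. Their fold changes equalled the differences of group means to within 8.4e-14, and the deposited score was 0 where the fold was under about 1.2. Genes with a deposited adjusted p under 0.05 numbered 491 for KO against WT in set 3, 4741 in set 5, 4410 in set 6, 5716 for sets 5 and 6 together, 76 for KO cells of sets 6 and 5, and 87 for WT cells of sets 6 and 5. A test against a minimum fold of 1.2 made here shared 491 of its 492 calls, 4728 of 4743, 4400 of 4419, 74 of 75 and 87 of 87 with them.

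Of 12547 genes, 12528 identifiers (99.8%) were matched to the name table, from GENCODE M21, and 10 symbols occurred more than once. Tests used limma 3.58.1 in R 4.3.3: 1 linear model with 6 group means, contrasts for KO against WT in each set and for the mean over sets, for the differences of these effects between sets, and for sets within a genotype, with moderated t-tests, a trend of variance with level, 12 residual degrees of freedom and Benjamini-Hochberg adjusted p under 0.05. The planned filter (a log2 value of 0 or more in at least 3 libraries) and the stricter one (2 or more in at least 3 libraries) removed no gene.

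Of 34 gene lists fixed beforehand, 32 had at least 3 measured members. Camera of limma on the deposited values compared each with all other genes, with a preset correlation of 0.01 and adjustment over the lists. The lists covered the Id and E protein family, programmes of T cells, growth and cell death, metabolism, stress responses, signalling, markers of 8 other cell types, sex-linked genes, and mitochondrially encoded genes and replication-dependent histones for RNA quality. Counts called "adjusted over the list alone" adjust p-values among the list's members only, on the deposited values. Median centring subtracts each library's median. An estimated correlation replaced the preset value as an alternative.

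Genes were named by a rule fixed beforehand. For each KO against WT comparison it names Id3; then, among genes past the test with no overlap of KO and WT values (for the mean, with the same direction in all sets) and a mean log2 value of 2 or more in the higher group, the 8 largest rises and 8 largest falls, leaving out genes without a proper symbol; then, in each list, the 3 called members with the smallest adjusted p in each direction. For sets and interactions it names the 5 largest in each direction. Other members of a fixed list may be named beside the list's count.

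Replicate numbers were checked for pairing through the correlation of deviations from group means. KO and WT libraries of a set were not paired (r from -0.08 to 0.18), nor KO sets 3 and 5 (0.03 to 0.15). For WT sets 3 and 5 r was 0.07 for equal and -0.05 to -0.03 for other numbers, so weak pairing stays open. Sets 5 and 6 were paired in KO (0.22 to 0.34) and WT cells (0.12 to 0.16), a hint from the data, not the labels.

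Alternatives fixed beforehand were a log2 difference of 1 or more, leaving out each library, median centring, quantile normalization, robust moderation, no trend, library weights, no filter, the stricter filter, the replicate number as a block, 1 added on the linear scale, and the compared groups alone; for lists also ranks and the estimated correlation. Chosen after seeing the data were a minimum fold of 1.2, alone and with centring, a mean log2 value of 6 or more (10056 genes), the block within each genotype, the average of sets 5 and 6 and the correlation of sets 5 and 6 by replicate number. Simulations changed 200 of 12547 genes. At log2 differences of 0.5, 1, 2 and 4 (50 each) 36%, 70%, 84% and 94% were found. Of 150 calls 5.33% were false, and an unchanged set gave 0. A shifted list and 0 of 30 others were called.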

Results

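The data were RNA-seq values of 18 libraries of mouse CD4 T cells, 3 libraries in each of 6 groups. Naive CD4 T cells had been activated with beads carrying antibodies to CD3 and CD28 and grown with IL2, IL12 and an antibody that blocks IL4. These conditions favour Th1 cells, the helper T cells that make interferon gamma. Cells lacking Id3 (KO) and wild-type cells (WT) were each sampled in 3 sets of libraries, which the labels number 3, 5 and 6. The labels do not say what the set numbers stand for. Contrast names in the authors' deposited table tie set 3 to 24 and sets 5 and 6 to 96, without a unit. The deposited values of 12547 genes were on a log2 scale and reached 19.5. Their median was 9.18, 9.57 and 9.66 in KO libraries of sets 3, 5 and 6, and 9.21, 9.18 and 9.25 in WT libraries. Because 97.0 to 98.4% of the sorted values were identical among the libraries of a group, the depth of the individual libraries was unknown. In a principal component analysis the first component held 54.1% of the variance and parted set 3 from sets 5 and 6, and the second held 19.7% and parted KO from WT libraries.

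Id3, the deleted gene, encodes an inhibitor that binds E proteins and keeps these transcription factors from DNA. Its mean log2 value was 3.05 ± 0.79 (SD, n = 3) in KO and 9.81 ± 0.24 (SD, n = 3) in WT cells of set 3. In set 5 the KO libraries stood at 2.02, 5.63 and 2.80 and the WT mean was 9.10 ± 0.37 (SD, n = 3). In set 6 the means were 3.48 ± 2.16 in KO and 9.18 ± 0.30 in WT cells (SD, n = 3 each). No KO library lay above 5.63 and no WT library below 8.85, so every library carried the level its label called for. Id3 differed from WT by -6.76 in set 3, -5.62 in set 5 and -5.70 in set 6 (SE 0.89 each; adjusted p = 0.000188, 4.99e-05 and 4.84e-05). Id2, a relative of Id3, rose in all 3 sets, by 1.32, 1.31 and 1.25 (SE 0.16 each; adjusted p = 8.91e-05, 3.18e-06 and 6.08e-06). Among the 6 measured members of the Id and E protein list, Id2 rose and Id3, Tcf3 and Tcf12 fell in set 3, the same counts as adjusted over the list alone. The call on Tcf12 was lost without any 1 library of set 3 except KO replicate 2 (adjusted p from 0.079 to 0.201), after median centring (0.0765), after quantile normalization (0.125) and with the replicate number as a block (0.0941). In sets 5 and 6, 4 members rose and Id3 fell, as also adjusted over the list alone. Relative to the median of all genes, 2 members rose in set 5 (Id2 and Tcf4) and Id2 alone rose in set 6. The list as a whole was not shifted in any set (adjusted p = 0.475, 0.688 and 0.871).

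The comparison of KO with WT cells within a set asked which transcripts differ in Th1 cells that lack Id3. In set 3, cytokine genes of Th2 cells, the helper cells of allergic and anti-parasite responses, rose in KO cells grown under Th1 conditions. Il4 had a mean log2 value of 10.93 ± 0.78 in KO and 6.22 ± 1.23 in WT cells (SD, n = 3 each), a difference of 4.71 (SE 0.46; adjusted p = 1.28e-05). Il13 stood at 12.60 ± 1.05 and 7.64 ± 0.57 (SD, n = 3 each), a difference of 4.96 (SE 0.37; adjusted p = 9.46e-07), and Il5 rose by 4.11 (SE 0.36; adjusted p = 5.18e-06). Gata3, the transcription factor that directs the Th2 programme, rose by only 0.73 (SE 0.11; adjusted p = 0.000715). Of the 19 measured members of the Th2 programme list, 15 rose and 4 did not pass, with 18 rising when adjusted over the list alone. The list median was 2.69 (adjusted p = 3.72e-20, and adjusted p = 0.0121 with an estimated correlation). Of 7 markers of granulocytes and mast cells 3 rose, 5 adjusted over the list alone. Cpa3, a mast cell protease gene, rose by 4.29 (SE 0.56) and Mcpt8, a basophil protease gene, by 4.28 (SE 0.92).

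In all, 1427 of 12547 genes differed between KO and WT cells of set 3, 868 higher and 559 lower. The largest rises by the naming rule were Sprr2a2 (7.29), Smr3a (6.34), the mast cell tryptase Tpsb2 (5.60), the cytokine gene Il9 (5.52), the mast cell chymase Cma1 (5.39), the chemokine gene Ccl24 (5.26), Bpifa2 (5.14) and Il17a (4.99). Their SE ran from 0.42 to 1.11 and adjusted p from 1.03e-06 to 0.00607. Sprr2a2 belongs to a family of near-identical genes, so its value is uncertain. Apart from Id3, the largest falls were Drc1 (-3.51, SE 0.78), Ampd1 (-3.19, SE 0.43), Dapl1 (-3.10, SE 0.88), Sfn (-2.99, SE 0.14), Slc15a2 (-2.87, SE 0.60) and Adh1 (-2.78, SE 0.61). Dcdc2b was at the lowest value in all 3 KO libraries and averaged 3.87 in WT cells. The call on Dapl1 was lost without KO replicate 1, KO replicate 3 or any 1 WT replicate (adjusted p from 0.0601 to 0.139). That on Dcdc2b was lost without any 1 KO replicate and without WT replicate 2 or 3 (0.0518 to 0.129).

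Genes of other effector programmes also rose in set 3. Of 18 measured Th17 programme genes, 12 rose and 6 did not pass, the same number adjusted over the list alone, with a median of 1.83 (adjusted p = 2.15e-12, 0.0769 with an estimated correlation). Il17f rose by 4.11 (SE 0.56; adjusted p = 0.000252) and Csf2, which encodes GM-CSF, by 4.03 (SE 0.43; adjusted p = 3.36e-05). Of 23 cytotoxic molecules, 15 rose, also adjusted over the list alone, and none fell (adjusted p = 8.13e-13, 0.0769 with an estimated correlation). Gzmc rose by 4.56 (SE 0.48), Gzma by 3.19 (SE 0.55) and Gzmb, which encodes granzyme B, by 1.87 (SE 0.26). Of 25 Th1 programme genes, 11 rose and none fell, or 12 and 2 adjusted over the list alone (adjusted p = 6.88e-06, 0.102 with an estimated correlation). The chemokine receptor gene Cxcr6 rose by 3.48 (SE 0.29; adjusted p = 3.3e-06), Ly6c2 by 2.87 (SE 0.32; adjusted p = 5.67e-05) and Ccl5 by 2.24 (SE 0.29; adjusted p = 0.000183). Tbx21, the gene of the Th1 transcription factor T-bet, differed by -0.44 (SE 0.15) and did not pass. Inhibitory receptors and exhaustion genes rose in 7 of 23 cases and fell in 1, or 7 and 2 adjusted over the list alone (adjusted p = 0.000408, 0.102 with an estimated correlation). Entpd1 rose by 2.72 (SE 0.25), Havcr2 by 2.21 (SE 0.41) and Tigit by 2.21 (SE 0.40). The 1 fall was lost without KO replicate 1 or 3 or WT replicate 1 or 2. Of 22 tissue residency and homing genes, 8 rose and 1 fell, or 9 and 1 adjusted over the list alone (adjusted p = 6.88e-06, 0.0769 with an estimated correlation). Itgae, which encodes CD103, rose by 2.85 (SE 0.42). Without KO replicate 1, the counts that rose were 6 for the Th1 list and 5 for the homing list, which also fell to 5 without WT replicate 1.

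Genes of naive and memory cells fell and genes of the cell cycle rose in KO cells of set 3. Of 28 measured naive, memory and stem-like genes, 11 fell and none rose, or 14 and 1 adjusted over the list alone (adjusted p = 3.32e-05, 0.102 with an estimated correlation). Nsg2 fell by 1.87 (SE 0.26), and Tcf7 and Lef1, transcription factor genes of naive T cells, by 0.91 (SE 0.17) and 0.89 (SE 0.13). Of 40 proliferation genes, 25 rose and 1 fell, or 29 and 3 adjusted over the list alone (adjusted p = 8.18e-14, 0.137 with an estimated correlation). Ube2c, which drives the exit from mitosis, rose by 1.44 (SE 0.21) and Top2a, a DNA topoisomerase gene, by 0.70 (SE 0.15). The 1 fall was lost without any 1 library. Without KO replicate 1, 6 naive genes fell and 13 proliferation genes rose; 16 proliferation genes rose without KO replicate 3, and 6 naive genes fell without WT replicate 1. Of 22 NF-kB targets, 9 rose and 1 fell, or 10 and 1 adjusted over the list alone (adjusted p = 0.000174, 0.137 with an estimated correlation). Without KO replicate 1, 3 rose, and the 1 fall was lost without KO replicate 1 or 2 or WT replicate 1 or 3. Of 16 regulatory T cell genes, 4 rose and 2 fell, or 5 and 2 adjusted over the list alone (adjusted p = 0.0269, 0.453 with an estimated correlation). Without KO replicate 1 or WT replicate 1, 2 rose and 1 fell, and 1 fell without WT replicate 2. Of 16 follicular helper genes, 4 rose and 3 fell, or 6 and 5 adjusted over the list alone (adjusted p = 0.267). Of 23 cholesterol synthesis genes, 3 fell and none rose, or 4 and none adjusted over the list alone (adjusted p = 0.000565, 0.426 with an estimated correlation). The number falling was 0 without KO replicate 2 or 3 or WT replicate 1, 1 without KO replicate 1 or WT replicate 3, and 5 without WT replicate 2.

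Markers of other cell types also stood higher in KO cells of set 3. B cell markers rose in 7 of 9 cases (9 adjusted over the list alone; adjusted p = 1.03e-06, 0.102 with an estimated correlation). Dendritic cell markers rose in 6 of 8 (7 adjusted over the list alone; adjusted p = 6.88e-06, 0.0769 with an estimated correlation) and erythroid markers in 4 of 6 (6 adjusted over the list alone; adjusted p = 1.88e-05, 0.0121 with an estimated correlation). Granulocyte and mast cell markers had adjusted p = 2.85e-05, 0.0121 with an estimated correlation. Cd79a, a B cell receptor component, rose by 2.50 (SE 0.63), a call lost without KO replicate 1 (adjusted p = 0.0781). Zbtb16, which encodes the NKT cell factor PLZF, rose by 4.02 (SE 0.56). The γδ and NKT cell list had 2 of 3 genes rising, also adjusted over the list alone (adjusted p = 0.0083, 0.102 with an estimated correlation). The macrophage and monocyte list had 3 rising and 1 falling of 12, or 4 and 1 adjusted over the list alone (adjusted p = 0.0563). None of 9 NK cell markers passed (adjusted p of the list 0.0358, 0.366 with an estimated correlation), and neither of the 2 CD8 markers did. Single libraries decided these marker counts: without KO replicate 1, 1 B cell, 1 dendritic cell, 1 erythroid, 1 macrophage and 1 γδ or NKT marker rose. The B cell count was 2 without WT replicate 1 or 2. The dendritic cell count was 1 without WT replicate 1 and 3 without WT replicate 3. The erythroid count was 1 without WT replicate 1 and 2 without KO replicate 3 or WT replicate 3. The macrophage count was 0 without KO replicate 3 and 1 without WT replicate 2 or 3. The macrophage fall was lost without any 1 library except KO replicate 2, and the γδ and NKT count was 1 without any 1 of KO replicate 3 and the 3 WT replicates. Of the 13 mitochondrially encoded genes, a sign of RNA quality, none passed (list median 0.02), and no sex-linked gene of the list was measured. Of 19 replication-dependent histones, also a sign of RNA quality, 3 rose, or 3 with 1 falling adjusted over the list alone (adjusted p = 0.0281, 0.422 with an estimated correlation). Without WT replicate 2, 1 histone gene rose, and without KO replicate 2, 1 fell. By limma, 23 of 32 lists were shifted in set 3 with the preset correlation and 3 with an estimated one. The count of called genes was 666 without KO replicate 1, 918 without KO replicate 3 and 872 without WT replicate 1.

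**Figure D1:**
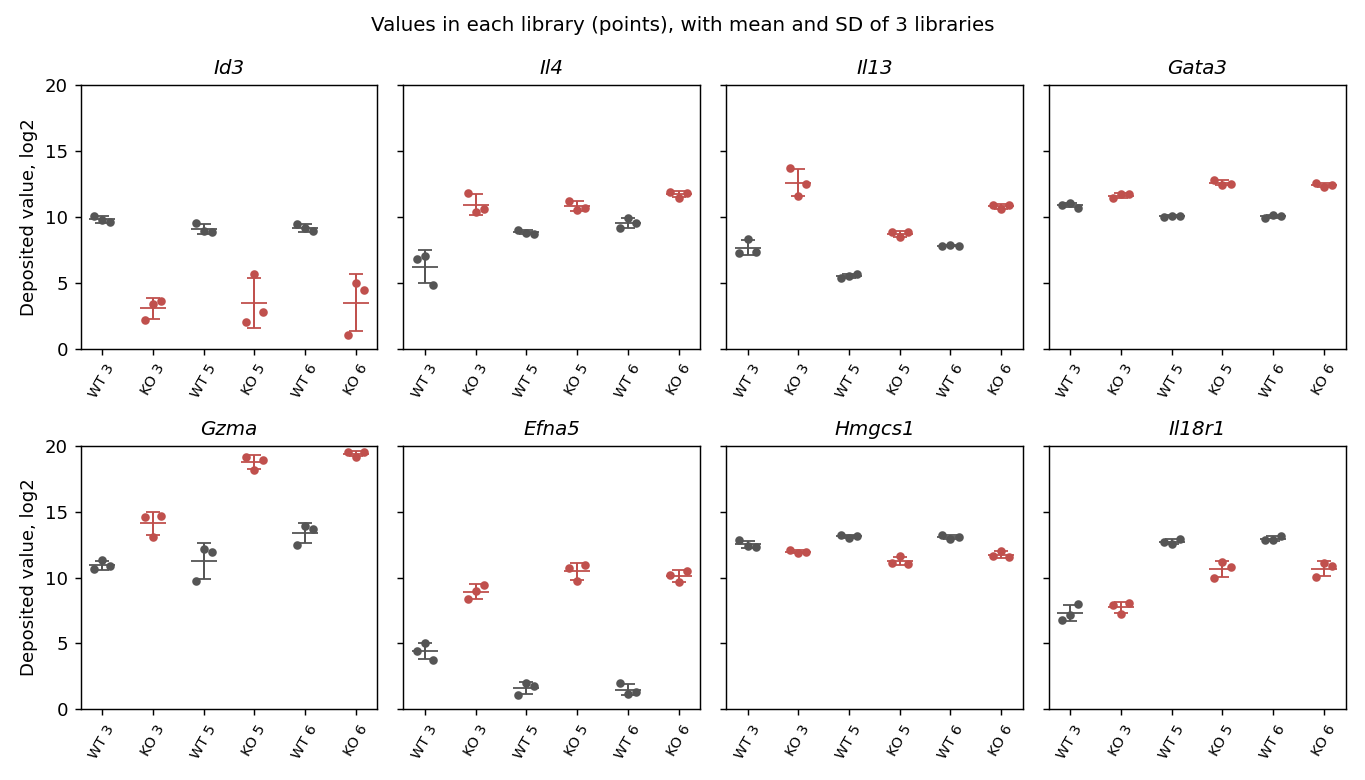
Deposited log2 values of 8 genes in each of the 18 libraries (points), with the mean and SD of 3 libraries per group (horizontal and vertical lines); WT is grey, KO is red, and the number is the set. Id3 lay at 5.63 or lower in KO and at 8.85 or higher in WT libraries, and Il4 averaged 10.93 in KO against 6.22 in WT cells of set 3.

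In sets 5 and 6 most genes stood higher in KO cells, and the median difference over all genes was 0.39 in set 5, 0.42 in set 6, -0.07 in set 3 and 0.26 for the mean over sets. List counts of sets 5 and 6 are therefore relative to the median of all genes (each library centred on its median). Counts as deposited stand beside them. List p-values and single-gene differences use deposited values. Relative to the median library value the latter are lower by 0.39 in set 5 and by 0.41 in set 6. In set 5, 7299 genes differed, 6285 higher and 1014 lower, and after centring 6218 differed, 3120 higher and 3098 lower. Of these, 4134 had the same call and direction on both scales. In set 6, 7336 genes differed, 6760 higher and 576 lower, against 4669 after centring, 2353 higher and 2316 lower, and 2929 were shared in call and direction.

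KO cells of set 5 combined a raised Th2 programme with lower transcripts of cholesterol synthesis. Gata3 had a mean log2 value of 12.58 ± 0.20 in KO and 10.05 ± 0.06 in WT cells (SD, n = 3 each), a difference of 2.52 (SE 0.11; adjusted p = 1.16e-09). Il13 rose by 3.20 (SE 0.37), Il5 by 2.90 (SE 0.36) and Epas1, which encodes the hypoxia-inducible factor HIF-2α, by 5.89 (SE 0.45; adjusted p = 4.76e-08). Of 19 Th2 programme genes, 17 rose and none fell after centring, 18 as deposited and 18 adjusted over the list alone. The centred median was 2.33 (adjusted p = 0.000793, 0.665 with an estimated correlation). Of the 7 granulocyte and mast cell markers, 1 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.177). The 1 that rose became 2 without any 1 KO replicate, and the 2 that fell became 1 without KO replicate 1. Of 23 cholesterol synthesis genes, 21 fell and none rose, 19 as deposited and 19 adjusted over the list alone. The centred median was -1.28 (adjusted p = 7.16e-20, 0.278 with an estimated correlation). Hmgcs1, the synthase at the start of the pathway, fell by 1.88 (SE 0.16; adjusted p = 1.24e-07), Pmvk by 1.33 (SE 0.14), Sqle by 1.25 (SE 0.14) and Idi1 by 1.24 (SE 0.12).

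The largest rises in set 5 by the naming rule included the ephrin gene Efna5 at 8.86 (SE 0.41; adjusted p = 1.16e-09), with means of 10.48 in KO and 1.63 in WT cells, and Gzma, which encodes granzyme A, at 7.46 (SE 0.55; adjusted p = 3.39e-08), with means of 18.75 ± 0.53 and 11.28 ± 1.36 (SD, n = 3 each). Cstdc4 (6.99), Il1r2, a decoy receptor of IL1 (6.60), Penk, which encodes proenkephalin (6.55), Tspan9 (6.29) and Serpinf1 (6.21) followed, with SE from 0.36 to 1.25. Csta2 was at the lowest value in all 3 WT libraries and averaged 10.63 in KO cells; Csta2 and Cstdc4 are near-identical cystatin genes, so their values are uncertain. The largest falls besides Id3 were Pitx1 (-5.79, SE 0.37), Gldc (-5.09, SE 0.51), Ubd (-5.06, SE 0.68), the chemokine receptor gene Ccr10 (-4.69, SE 0.58), Acsl6 (-4.35, SE 0.31), B3galnt1 (-4.09, SE 0.49) and Dapl1 (-4.02, SE 0.88).

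NF-kB targets rose in set 5: 17 of 22 rose and 1 fell after centring, 19 and none as deposited and adjusted over the list alone. The centred median was 0.90 (adjusted p = 0.000234, 0.518 with an estimated correlation). Cd83 rose by 4.23 (SE 0.57), Tnfaip3, which encodes the inhibitor A20, by 2.67 (SE 0.17), Birc3 by 1.76 (SE 0.13) and Nfkbia by 1.75 (SE 0.13). Of 23 cytotoxic molecules, 13 rose and 2 fell, 15 and none as deposited and adjusted over the list alone (adjusted p = 0.259). Besides Gzma, Gzmc rose by 2.16 (SE 0.48), while Gzmb differed by 0.07 (SE 0.26) and did not pass. Inhibitory receptors and exhaustion genes rose in 14 of 23 cases and fell in 2, 15 and 2 as deposited and adjusted over the list alone (adjusted p = 0.353). Tigit rose by 3.10 (SE 0.40), and Batf and Irf4, transcription factor genes of effector T cells, by 2.90 (SE 0.17) and 2.18 (SE 0.10). Of 16 regulatory T cell genes, 8 rose and none fell, 9 and none as deposited and adjusted over the list alone (adjusted p = 0.189). The Th1 programme went both ways: 5 of 25 rose and 11 fell, 9 and 5 as deposited and 8 and 5 adjusted over the list alone (adjusted p = 0.0208, downward, 0.744 with an estimated correlation). The list had a median of 0.00 and a mean of 0.15 as deposited, and a centred median of -0.38. Il12rb1, a subunit of the IL12 receptor, rose by 1.80 (SE 0.12), Il18r1, a subunit of the IL18 receptor, fell by 2.07 (SE 0.34) and Ly6c2 fell by 1.76 (SE 0.32), and Tbx21 differed by 0.36 (SE 0.15) and did not pass. Without KO replicate 1 or WT replicate 2 it passed (adjusted p = 0.00601 and 0.0336).

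Of 28 naive, memory and stem-like genes in set 5, 8 rose and 10 fell after centring, 16 and 6 as deposited and 16 and 7 adjusted over the list alone (adjusted p = 0.353). Myb rose by 2.75 (SE 0.32) and Txk fell by 1.63 (SE 0.23). The follicular helper list had 6 rising and 4 falling of 16, 10 and 3 as deposited and 10 and 4 adjusted over the list alone (adjusted p = 0.559). Il21 rose by 5.99 (SE 0.44). Th17 programme genes rose in 7 of 18 cases and fell in 2, 9 and 1 as deposited and adjusted over the list alone (adjusted p = 0.846), with 2 falling as deposited without KO replicate 2. Homing genes rose in 9 of 22 and fell in 5, 11 and 3 as deposited and adjusted over the list alone (adjusted p = 0.688). Rgs1 rose by 3.99 (SE 0.28) and Itgae by 3.86 (SE 0.42). Of 40 proliferation genes, 25 fell and none rose after centring, but 7 rose and 3 fell as deposited, or 6 and none adjusted over the list alone (adjusted p = 0.000265, downward, 0.778 with an estimated correlation). The 3 became 11 without KO replicate 2, 1 without WT replicate 2 and 0 without any 1 of the other 4 libraries. Of the markers of other cells, dendritic cell markers rose in 4 of 8 cases on both scales (Cd74 by 2.71, SE 0.37) and macrophage markers in 4 of 12 (5 as deposited). NK markers rose in 2 of 9 (3 as deposited, which became 1 without KO replicate 3 or WT replicate 1 and 6 without WT replicate 2), and γδ and NKT markers in 1 of 3. The counts as deposited held when adjusted over the list alone. Of 6 erythroid markers 1 fell, none adjusted over the list alone (adjusted p = 0.0208, 0.278 with an estimated correlation), and the 1 was lost without KO replicate 2 or 3 or WT replicate 2. No B cell or CD8 marker passed after centring, but 1 of 9 and 1 of 2 rose as deposited, 0 and 1 adjusted over the list alone. The B cell marker was lost without KO replicate 1 or 2 or WT replicate 1 or 3. By limma, 12 lists were shifted with the preset correlation and 0 with an estimated one.

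In set 6, KO cells again carried higher Th2 and NF-kB transcripts and lower transcripts of cholesterol synthesis. Gata3 rose by 2.40 (SE 0.11; adjusted p = 1.27e-09), Epas1 by 6.36 (SE 0.45; adjusted p = 4.51e-08), Il13 by 2.99 (SE 0.37) and Il4 by 2.18 (SE 0.46). Of 19 Th2 programme genes, 15 rose and none fell after centring, 17 as deposited and 18 adjusted over the list alone. The centred median was 1.81 (adjusted p = 0.00474, 0.567 with an estimated correlation). Of 7 granulocyte and mast cell markers, 1 rose and 2 fell, 2 and 2 as deposited and adjusted over the list alone (adjusted p = 0.00776, downward, 0.344 with an estimated correlation). The 2 rising became 0 without WT replicate 2 and 1 without any 1 other library of the set. Of 23 cholesterol synthesis genes, 19 fell and none rose, 15 and 1 as deposited and 15 and 2 adjusted over the list alone. The centred median was -0.87 (adjusted p = 1.9e-13, 0.378 with an estimated correlation). Hmgcs1 fell by 1.33 (SE 0.16) and Pmvk by 0.88 (SE 0.14). NF-kB targets rose in 13 of 22 cases and fell in 1, 19 and none as deposited and adjusted over the list alone (adjusted p = 0.00138, 0.519 with an estimated correlation). Tnfaip3 rose by 2.62 (SE 0.17).

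The Th1 programme and the naive genes stood lower in KO cells of set 6. Of 25 Th1 programme genes, 12 fell and 3 rose after centring, 9 and 8 as deposited and adjusted over the list alone. The centred median was -0.78 (adjusted p = 3.95e-05, 0.434 with an estimated correlation). Il18r1 fell by 2.27 (SE 0.34; adjusted p = 3.67e-05), Ly6c2 by 1.28 (SE 0.32), Hopx by 1.15 (SE 0.19) and Cxcr3, a chemokine receptor gene of Th1 cells, by 0.80 (SE 0.20), whereas Il12rb1 rose by 1.39 (SE 0.12). The 8 rising as deposited became 5 without KO replicate 3 or WT replicate 3. Of 28 naive, memory and stem-like genes, 13 fell and 3 rose, 9 and 8 as deposited and adjusted over the list alone (adjusted p = 7.6e-05, 0.378 with an estimated correlation). Igfbp4 fell by 3.16 (SE 0.46), Txk by 2.17 (SE 0.23) and Lef1 by 0.59 (SE 0.13). Of 23 cytotoxic molecules, 5 rose and 4 fell, 5 and 2 as deposited and 5 and 1 adjusted over the list alone (adjusted p = 0.231). Gzma rose by 6.03 (SE 0.55; adjusted p = 3.43e-07), with means of 19.38 ± 0.18 in KO and 13.36 ± 0.76 in WT cells (SD, n = 3 each). The 2 cytotoxic genes that fell as deposited became 1 without any 1 library of the set except KO replicate 3.

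Proliferation and further T cell programmes of set 6 did not pass as whole lists, though single genes differed. Inhibitory receptors and exhaustion genes rose in 12 of 23 cases and fell in 2, 14 and 2 as deposited and 15 and 2 adjusted over the list alone (adjusted p = 0.824). Batf rose by 2.95 (SE 0.17) and Irf4 by 1.83 (SE 0.10), and Btla and Tox fell by 2.35 (SE 0.28) and 2.17 (SE 0.32). Regulatory T cell genes rose in 8 of 16 cases and fell in 2, 11 and none as deposited and adjusted over the list alone (adjusted p = 0.423). Th17 programme genes rose in 8 of 18 cases and none fell, 11 as deposited and adjusted over the list alone (adjusted p = 0.657). Il17a rose by 6.65 (SE 0.86). Homing genes rose in 9 of 22 cases and fell in 5, 9 and 3 as deposited and adjusted over the list alone (adjusted p = 0.231). Follicular helper genes rose in 5 of 16 and fell in 4, 8 and 4 as deposited and adjusted over the list alone (adjusted p = 0.232). Proliferation genes fell in 3 of 40 and none rose, none and 16 as deposited, or none and 14 adjusted over the list alone (adjusted p = 0.824). The largest rises were Efna5 (8.61), Fabp4 (7.12), Fam240a (6.66), Il17a (6.65), Epas1 (6.36), Cstdc4 (6.29) and Gzma (6.03), with SE from 0.41 to 1.25, and Pth, at the lowest value in all WT libraries and at a mean of 7.21 in KO cells. The largest falls besides Id3 were Pitx1 (-4.91), Drc1 (-4.74), Ubd (-3.81), Ggt1 (-3.70), Gldc (-3.58), Setbp1 (-3.44) and Slc15a1 (-3.40), with SE from 0.28 to 0.78. Of the markers of other cells, macrophage markers rose in 4 of 12 cases and fell in 1, 5 and none as deposited and 4 and none adjusted over the list alone, and 1 fell as deposited without WT replicate 2. Dendritic cell markers rose in 1 of 8, 3 as deposited and adjusted over the list alone, and 1 as deposited without KO replicate 1. No B cell, NK or CD8 marker passed on either scale (adjusted p of the NK list 0.0451, downward, 0.567 with an estimated correlation). As deposited, 1 B cell marker rose without KO replicate 3 or WT replicate 2, 1 NK marker rose without KO replicate 1 or WT replicate 1 or 2, and 1 NK marker fell without KO replicate 3. Of the CD8 markers 1 rose without KO replicate 1 and 1 fell without WT replicate 1. Of 3 γδ and NKT markers 1 rose, 2 as deposited and adjusted over the list alone (adjusted p = 0.886), and the 2 became 1 without KO replicate 2 or 3 or WT replicate 1 or 3. Of 6 erythroid markers 1 rose and 1 fell on both scales, 1 and none adjusted over the list alone (adjusted p = 0.231). Without KO replicate 3, 2 erythroid markers rose, and the fall was lost without any 1 library except KO replicate 1. Of 19 replication-dependent histones, 1 rose and 1 fell, 2 and none as deposited and 1 and none adjusted over the list alone (adjusted p = 0.0115, downward, 0.567 with an estimated correlation). The 2 became 1 without KO replicate 1 or 2 or WT replicate 1 or 2, and 1 fell as deposited without KO replicate 1 or 2. Of 13 mitochondrial genes 6 fell and none rose, but none fell and 3 rose as deposited, none adjusted over the list alone (adjusted p = 0.155). The 3 became 0 without KO replicate 1 or 3, 5 without KO replicate 2 and 1 without WT replicate 3. In sets 5 and 6 the camera direction differed in sign from the centred median or mean for the follicular helper, homing, apoptosis, B cell and dendritic cell lists. In set 5 this also held for the naive, unfolded protein, NK and mitochondrial lists, and in set 6 for the cytotoxic, macrophage and erythroid lists. None of these lists was called by camera. Id3 gave the Id and E protein list a negative mean beside a positive median in both sets. By limma, 13 lists were shifted with the preset correlation and 0 with an estimated one.

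**Figure D2:**
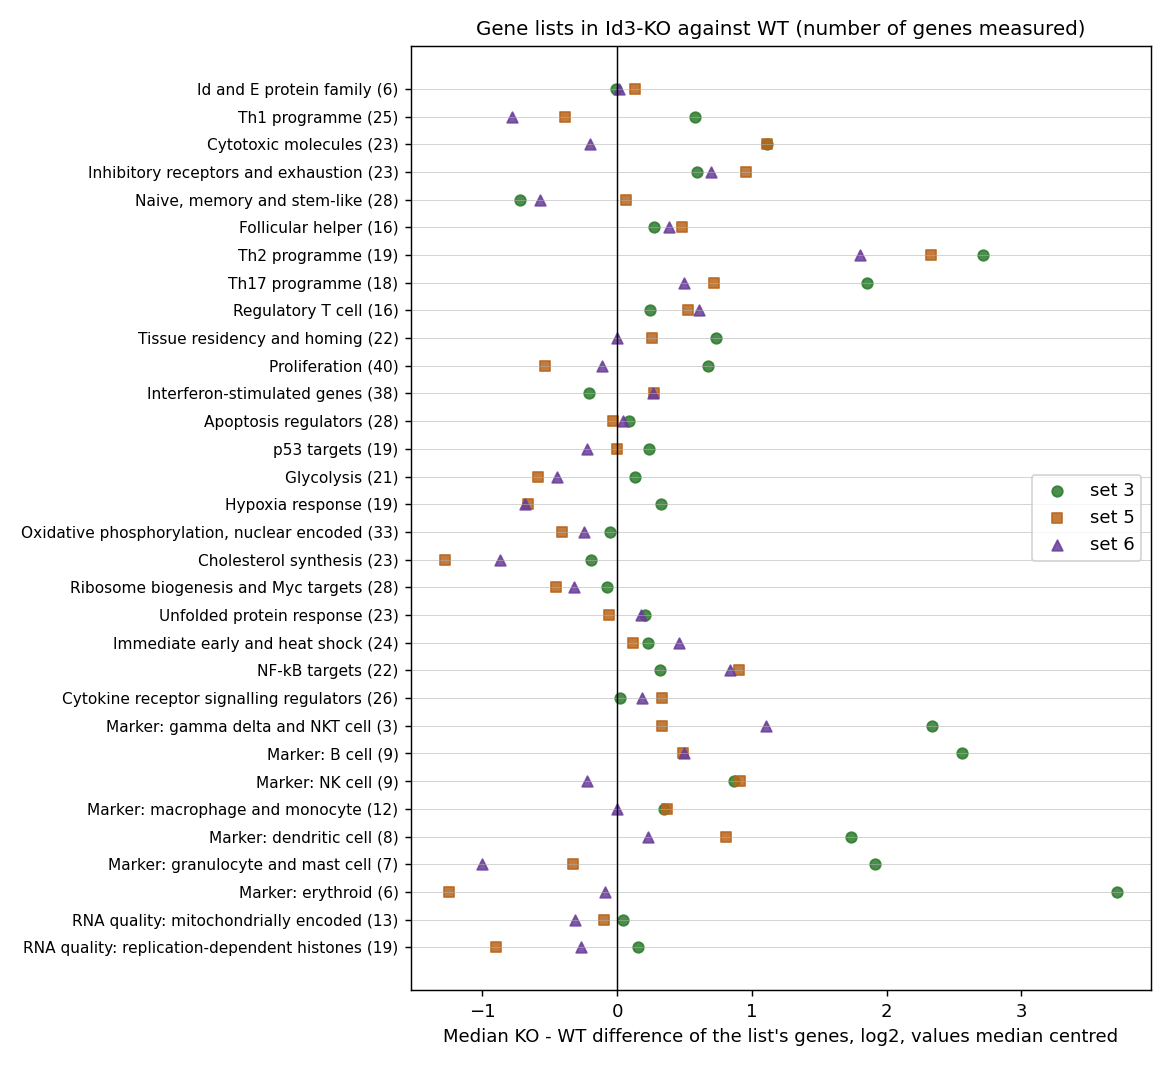
Median log2 difference between KO and WT cells over the members of each gene list (number measured in brackets), each library centred on its median, for sets 3 (circles), 5 (squares) and 6 (triangles). The Th2 programme lay at 2.72, 2.33 and 1.81, and cholesterol synthesis at -0.19, -1.28 and -0.87.

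For the mean of the KO effect over the 3 sets, Efna5 rose by 7.33 (SE 0.23; adjusted p = 4.28e-12), Gzma by 5.56 (SE 0.32), Epas1 by 4.98 (SE 0.26), Penk by 4.65 (SE 0.21) and Il1r2 by 4.52 (SE 0.37). Csta2, Cstdc4 and Il17a also were among the largest rises, but each was at the lowest value in all libraries of at least 1 WT group. The largest falls were Id3 (-6.03, SE 0.51), Drc1 (-3.59), Dapl1 (-2.88), Acsl6 (-2.66), the sialomucin gene Podxl (-2.44), Ggt1 (-2.29) and Slc15a1 (-2.26), with SE from 0.18 to 0.51; Pitx1 was also among them but lay at the lowest value in all libraries of set 3. All 19 Th2 programme genes rose as deposited and adjusted over the list alone, and 18 after centring (adjusted p = 5.29e-06, 0.382 with an estimated correlation). Of 23 cholesterol synthesis genes, 21 fell after centring, 19 as deposited and adjusted over the list alone (adjusted p = 1.28e-19, 0.382 with an estimated correlation). Of the markers of other cells, 5 of 9 B cell markers rose after centring, 8 as deposited and 9 adjusted over the list alone (adjusted p = 0.606), 4 of 12 macrophage markers, 6 as deposited and adjusted over the list alone (adjusted p = 0.83), and 4 of 8 dendritic cell markers on both scales and adjusted over the list alone (adjusted p = 0.559). Of 7 granulocyte and mast cell markers 2 rose and 2 fell, 3 and 2 as deposited and 4 and 2 adjusted over the list alone (adjusted p = 0.562). Histones fell in 6 of 19 cases, but 3 fell and 4 rose as deposited, 1 and 3 adjusted over the list alone (adjusted p = 0.00916, 0.774 with an estimated correlation). The 3 became 1 without KO replicate 2 of set 3 or KO replicate 3 of set 5 or 6, and 1 macrophage marker fell without WT replicate 2 of set 6. Of 13 mitochondrial genes 3 fell, but 5 rose as deposited and adjusted over the list alone (adjusted p = 0.83). Over all genes, 7964 were called, 6917 higher and 1047 lower, and after centring 6620, 3246 higher and 3374 lower. By limma, 12 lists were shifted with the preset correlation and 0 with an estimated one.

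Whether the KO effect differed between sets was tested with interactions. Against set 3, the effect in set 5 was more positive for Gask1a (5.45) and Gng4 (5.28), and for Csta2, Sval1 and Csta3. It was more negative for Ubd (-8.00), Ccr10 (-6.30), Serpinb1a (-6.03) and the stress gene Nupr1 (-6.02), with SE from 0.72 to 1.35, and for Sprr2a2. Against set 3, the effect in set 6 was more positive for Fam240a (5.79) and Ldhd (5.03), and for Sval1 and the fatty acid binding protein gene Fabp4. It was more negative for Ubd (-6.74), Hba-a1 (-6.59) and Samd3 (-5.65), with SE from 0.47 to 1.66, and for Sprr2a2 and Smr3a. Stfa2 averaged 5.98 in KO cells of set 6 and was at the lowest value in all libraries of WT cells of set 6 and of set 3. Csta2, Csta3, Stfa2, Sprr2a2 and Hba-a1 have near-identical copies, so their values are uncertain, and Csta2, Csta3, Sval1, Stfa2, Fabp4, Sprr2a2 and Smr3a were at the lowest value in all libraries of at least 1 compared group, so no fold is given. Proliferation genes had a more negative effect in 32 of 40 cases in set 5 and in 24 in set 6 after centring, and 1 in set 6 a more positive one. As deposited, 26 were lower and 7 higher in set 5, also adjusted over the list alone, and 12 lower and 8 higher in set 6, or 14 and 8 adjusted over the list alone (adjusted p = 1.79e-12 and 2.44e-07, and 0.468 and 0.323 with an estimated correlation). The 12 became 5 without KO replicate 1, 6 without KO replicate 3 and 22 without KO replicate 2 of set 3, and 7 without WT replicate 1 of set 3 or WT replicate 1 or 2 of set 6. The Th1 programme had a more negative effect in 11 of 25 cases and a more positive one in 2 in each comparison, 10 and 4 as deposited and adjusted over the list alone in set 5 and 10 and 5 in set 6 (adjusted p = 2.19e-05 and 4.91e-09, and 0.344 and 0.131 with an estimated correlation). The 5 became 3 without KO replicate 2, WT replicate 1 or WT replicate 3 of set 6. Granulocyte and mast cell markers had a more negative effect in 5 and 6 of 7 cases, on both scales and adjusted over the list alone (adjusted p = 0.000288 and 1.23e-06, and 0.0333 and 0.0075 with an estimated correlation), with 3 in place of 5 without WT replicate 2 of set 3.

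Other markers and signs of RNA quality also had different KO effects between these sets. Erythroid markers had a more negative effect in 5 of 6 cases in set 5 and in 2 in set 6, on both scales, 5 and 1 adjusted over the list alone (adjusted p = 2.25e-05 and 0.000176, and 0.017 and 0.0212 with an estimated correlation). The 2 became 1 without any 1 library of sets 3 and 6 except KO replicate 3 of either set and WT replicates 1 and 2 of set 6. Histones had a more negative effect in 8 and 3 of 19, 4 and 2 as deposited and 3 and 0 adjusted over the list alone (adjusted p = 2.63e-06 and 0.000358, and 0.3 and 0.262 with an estimated correlation). The 4 became 7 without KO replicate 2 of set 5. The 2 became 1 without KO replicate 2 or WT replicate 3 of set 3, or KO replicate 1, WT replicate 1 or WT replicate 2 of set 6. Of 13 mitochondrial genes, 1 in set 5 and 5 in set 6 had a more negative effect, but 3 and 0 a more positive one as deposited, 2 and 0 adjusted over the list alone (adjusted p = 0.807 and 0.0598). Of 12 macrophage markers, 2 had a more positive and 1 a more negative effect in set 5 (4 and 1 as deposited, 4 and 0 adjusted over the list alone) and 2 and 2 in set 6 (4 and 2 as deposited and adjusted over the list alone; adjusted p = 0.47 and 0.0598). The 1 was kept as deposited only without KO replicate 2 or WT replicate 1 or 2 of set 3, or KO replicate 2 or WT replicate 2 of set 5, and the 2 became 1 without KO replicate 1 or WT replicate 3 of set 3, or KO replicate 3 or WT replicate 2 of set 6.

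In all, 6276 genes differed in effect between sets 5 and 3, 5420 more positive and 856 more negative, and after centring 4659, 2343 more positive and 2316 more negative. Between sets 6 and 3 the numbers were 6314, 5798 and 516, and after centring 3022, 1597 and 1425. Between sets 6 and 5 limma called 0 genes, with 1320 at an unadjusted p under 0.05 and a smallest adjusted p of 0.148; 1 gene was called without WT replicate 3 of set 5 and 11 with the replicate numbers blocked within each genotype. Across genes, which are not independent replicates, the centred KO differences of sets 5 and 6 correlated with r = 0.81 (rank correlation 0.80), those of sets 3 and 5 with r = 0.21 (0.08) and those of sets 3 and 6 with r = 0.26 (0.14). Same-numbered libraries of sets 5 and 6 deviated together, so these sets are not independent. For differences between single KO and WT libraries of a number, r between sets 5 and 6 was 0.59 to 0.72 for the same number and 0.53 to 0.63 for other numbers. Sets 5 and 6 shared 1981 higher and 1970 lower calls, and 5 and 4 had opposite calls. Sets 3 and 5 shared 336 higher calls (228 for independent lists) and 104 lower ones (102). Of genes higher in set 3, 166 were lower in set 5 (226 for independent lists), and of genes lower in set 3, 121 were higher in set 5 (102). Sets 3 and 6 shared 300 (172) and 123 (76.0), and 96 (169) and 74 (77.3) were opposite.

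Between sets 5 and 3 of WT cells, transcripts of ribosome production fell and those of hypoxia, the cell cycle and histones rose. All 28 ribosome biogenesis and Myc targets fell, also adjusted over the list alone, with a median of -1.68 (adjusted p = 9.69e-12, 0.486 with an estimated correlation). Of 19 hypoxia response genes, 18 rose, also adjusted over the list alone, with a median of 2.21 (adjusted p = 9.93e-07, 0.486 with an estimated correlation). Of 40 proliferation genes 30 rose and 8 fell, or 31 and 8 adjusted over the list alone (adjusted p = 2.28e-07, 0.542 with an estimated correlation). Replication-dependent histones rose in 18 of 19 cases, also adjusted over the list alone (adjusted p = 9.74e-05, 0.486 with an estimated correlation). Markers of other cells moved both ways. All 9 NK cell markers fell (adjusted p = 0.00881, 0.496 with an estimated correlation), as did 7 of 8 dendritic cell markers with 1 rising (adjusted p = 0.107), all 3 γδ and NKT markers (adjusted p = 0.385), 4 of 6 erythroid markers (adjusted p = 0.123) and both CD8 markers. Of 13 mitochondrial genes, 8 fell and 1 rose (adjusted p = 0.107), and 5 fell without WT replicate 2 of set 3. Of 12 macrophage markers 5 rose and 4 fell (adjusted p = 0.74), and of 7 granulocyte and mast cell markers 3 rose and 1 fell (adjusted p = 0.38). These counts held when adjusted over the list alone. Of 9 B cell markers 1 rose and 4 fell, 3 adjusted over the list alone (adjusted p = 0.459). The 4 became 1 without WT replicate 3 of set 3 and 2 without WT replicate 2 of set 3 or WT replicate 1 of set 5. The 1 was lost without WT replicate 2 of set 3 or WT replicate 1 or 2 of set 5. Il2, the T cell growth factor gene, fell by 7.80 (SE 0.75; adjusted p = 1.5e-07), Lad1 by 8.06 (SE 0.60) and the urokinase receptor gene Plaur by 7.75 (SE 0.67), and Ccl22 averaged 8.41 in set 3 and was at the lowest value in all WT libraries of set 5. Nupr1 rose by 7.85 (SE 0.51), Pigz by 7.66 (SE 0.39), Sparc by 7.66 (SE 0.93) and the cell cycle inhibitor gene Cdkn2a by 7.37 (SE 0.44), and the agouti gene a averaged 11.01 in set 5 and was at the lowest value in all WT libraries of set 3. Exosc6, annotated as overlapping another gene and so uncertain, averaged 9.25 in set 3 and was at the lowest value in all libraries of sets 5 and 6. In all, 8479 genes differed, 3672 higher and 4807 lower.

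KO cells of sets 5 and 3 differed in a related way. Of 28 ribosome biogenesis and Myc targets, 27 fell, also adjusted over the list alone (adjusted p = 1.96e-17, 0.443 with an estimated correlation). Of 19 hypoxia response genes 16 rose, or 17 adjusted over the list alone (adjusted p = 0.0251, 0.679 with an estimated correlation), and 32 of 38 interferon-stimulated genes rose and 2 fell, also adjusted over the list alone (adjusted p = 0.000609, 0.659 with an estimated correlation). After centring these counts were 28, 16, and 31 and 3. All 6 erythroid markers fell on both scales and adjusted over the list alone (adjusted p = 0.000507, 0.0416 with an estimated correlation). So did 7 of 8 dendritic cell markers (adjusted p = 0.00253, 0.443 with an estimated correlation). Of 9 NK cell markers 8 fell after centring, 7 as deposited and adjusted over the list alone (adjusted p = 0.00157, 0.443 with an estimated correlation). Of 9 B cell markers 7 fell, 6 as deposited and 7 adjusted over the list alone (adjusted p = 0.00431, 0.515 with an estimated correlation), and 1 rose without KO replicate 1 of set 3. Of 7 granulocyte and mast cell markers 5 fell and 2 rose on both scales and adjusted over the list alone (adjusted p = 0.144). Of 12 macrophage markers 5 fell and 5 rose, 4 and 5 as deposited and adjusted over the list alone (adjusted p = 0.665). All 3 γδ and NKT markers (adjusted p = 0.0821) and both CD8 markers fell, 2 and 1 as deposited and adjusted over the list alone. Of 13 mitochondrial genes 9 fell and 1 rose, 3 and 1 as deposited and adjusted over the list alone (adjusted p = 0.0944), with 2 rising without KO replicate 2 of set 5. Hbb-bs, a haemoglobin gene with a near-identical copy, fell by 9.25 (SE 1.15), Il9 by 9.09 (SE 1.09) and Il22 by 8.19 (SE 0.94), and Hbb-bt and the carbonic anhydrase gene Car1 averaged 9.58 and 9.26 in set 3 and were at the lowest value in all KO libraries of set 5. Enah, a regulator of actin filaments, rose by 7.44 (SE 0.33), Mcf2l by 6.90 (SE 0.35), Drc1 by 6.75 (SE 0.78), Pigz by 6.47 (SE 0.39) and Csta2 by 6.47 (SE 0.92). In all, 9180 genes differed, 6248 higher and 2932 lower, and after centring 8949, 4466 higher and 4483 lower. With centring, WT and KO cells shared 2939 higher and 3394 lower genes between sets 5 and 3, where independent lists would share 1362 and 1651, and the differences correlated across genes with r = 0.74.

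Between sets 6 and 5 fewer genes differed. In WT cells Ifitm6 rose by 4.66 (SE 0.81), Slc5a11 by 3.85 (SE 0.72), Esm1 by 3.76 (SE 0.73) and Serpinf1 by 3.53 (SE 0.69), and Csta2 averaged 6.34 in set 6 and was at the lowest value in all WT libraries of set 5. In WT cells Pdlim4 (-3.24, SE 0.30), Sorcs2 (-2.36, SE 0.35), Plat (-2.09, SE 0.46) and Tex45 (-1.90, SE 0.41) fell. In KO cells Il17a rose by 5.57 (SE 0.86), Fabp4 by 4.75 (SE 0.88), the chemokine receptor gene Ccr6 by 3.66 (SE 0.38) and Il3 by 3.61 (SE 0.74), and Grp averaged 5.95 in set 6 and was at the lowest value in all KO libraries of set 5. In KO cells Gprc5b (-2.99, SE 0.39), Pdlim4 (-2.95, SE 0.30), Tm4sf5 (-2.52, SE 0.79) and Tcea3 (-2.47, SE 0.53) fell. Without 1 library some of these calls were lost: Slc5a11 without WT replicate 2 of set 6 (adjusted p = 0.056), Serpinf1 without WT replicate 2 or 3 of set 6 (0.0673 and 0.0516), and Esm1 without WT replicate 1 of set 5 or WT replicate 2 or 3 of set 6 (0.0645, 0.0554 and 0.0667). Plat was lost without WT replicate 1 or 3 of set 5 or WT replicate 2 or 3 of set 6 (0.0712 to 0.105), and Tex45 without WT replicate 1 or 2 of set 5 or WT replicate 2 or 3 of set 6 (0.0608 to 0.107). Tm4sf5 was lost without KO replicate 1 or 3 of set 5 or KO replicate 2 or 3 of set 6 (0.0669 to 0.211), and also after median centring (0.0549) and with 1 added on the linear scale (0.0531), and Tcea3 without KO replicate 3 of set 5 (0.0549). The WT count was 423, 378 higher and 45 lower, and after centring 258, 187 and 71; with the replicate numbers blocked, which pair the libraries of sets 5 and 6, it was 740. It was 129, 238 and 217 without WT replicates 1, 2 and 3 of set 5, and 118 and 113 without replicates 2 and 3 of set 6. The KO count was 1501, 1246 higher and 255 lower, and after centring 943, 486 and 457; it was 955 and 589 without KO replicates 1 and 3 of set 5, and 693 and 798 without replicates 1 and 2 of set 6.

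**Figure D3:**
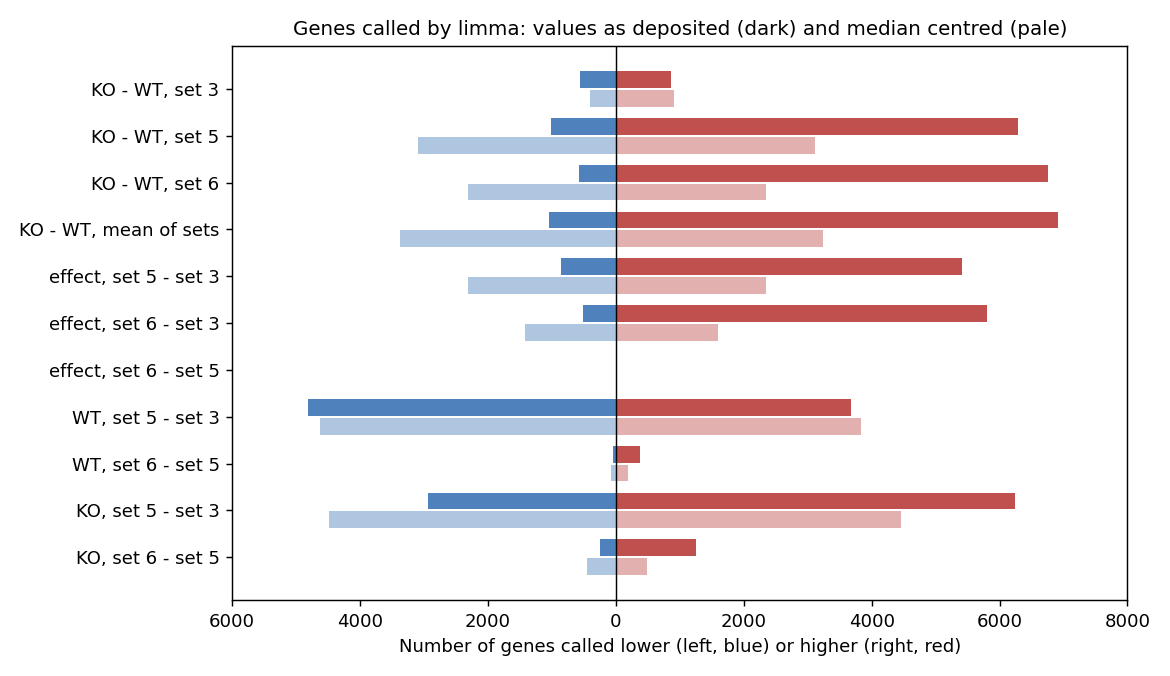
Number of genes called lower (blue, to the left) and higher (red, to the right) by limma in each comparison, with the values as deposited (dark) and with each library centred on its median (pale); "effect" stands for a difference of KO effects between sets. As deposited, 6285 genes were higher and 1014 lower in KO cells of set 5, and 3120 and 3098 after centring.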

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

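The tests of a scale factor, of the percentiles, of markers by bootstrap and of a technical difference between sets were chosen only after the result was seen, while the interactions, median centring and the matched random lists were planned. What drew attention was a difference between sets: by the interaction test of limma the KO effect differed between sets 5 and 3 for 6276 genes and between sets 6 and 3 for 6314 genes. Of 104 genes named for KO effects, which favours such differences, 83 passed an interaction on both scales, 61 in both sets 5 and 6. The larger median-centred difference is given. Groups of 3 libraries are too small for a test of single libraries as outliers.

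The effect was more positive in set 5 than in set 3 for Serpinf1 (4.45), Il1r2 (4.08), Efna5 (3.92), Penk (3.91), Gzma (3.86), Ifngr2 (3.72), Tspan9 (3.53), Il21 (3.52) and Rgs1 (2.93). The same held for Cd83 (2.63), Irgm1 (2.08), Irf1 (1.95), Myb (1.83), Irf4 (1.66), Jak2 (1.53), Birc3 (1.45), Gata3 (1.38), Sfn, Il12rb1 and Tcf4 (1.27 each). Smaller differences were those of Jun (1.23), Tnfaip3 (1.1), Mcl1 and Socs1 (1.05 each), Tcf7 (1.03), Hif1a (0.82), Dnajb9 (0.80), Tcf3 (0.38) and Tcf12 (0.36). It was more negative in set 5 for Ubd (-8.41), Ccr10 (-6.72), Gldc (-5.90), Csf2 (-5.33), Ly6c2 (-5.05), and Podxl (-4.28). Cpa3 (-3.70), Il17f (-3.55), Il4 (-3.13), Acsl6 (-2.92), Btla (-2.67), Gzmb (-2.21) and Ube2c (-1.96) followed. The cholesterol synthesis genes Hmgcs1 (-1.72), Idi1 (-1.45), Sqle (-1.28) and Pmvk (-1.27), and Slc2a3 (-1.72), Vegfa (-1.53), Top2a (-1.32) and Nop16 (-0.97) were also more negative.

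In set 6 the effect was more positive than in set 3 for Fam240a (5.35), Ampd1 (3.90), Epas1 (3.23), Adh1 (2.84), Slc15a2 (2.52), Batf (1.70), Nfkbia (1.04) and Junb (0.58). It was more negative for Mcpt8 (-5.31), Setbp1 (-4.61), Cxcr6 (-4.54), Ggt1 (-4.04), Gzmc (-4.03) and Slc15a1 (-3.41). Ccl5 (-3.38), Il18r1 (-3.13), Cxcr3 (-2.61), Igfbp4 (-2.42), Il13 (-2.41), Hopx (-2.16), Txk (-2.08), Il5 (-2.0) and Entpd1 (-1.65) were more negative as well. Genes at the lowest value in all libraries of at least 1 compared group have values that rest on it and are no measured folds: Csta2 (6.06), Cma1 (-6.27), Pitx1 (-6.16), Tpsb2 (-6.03) and B3galnt1 (-4.24) in set 5, and Fabp4 (4.65), Sprr2a2 (-7.10), Smr3a (-6.76), Bpifa2 (-5.11) and Ccl24 (-4.73) in set 6.

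One scale factor for all genes was excluded as the whole cause of this difference between sets, because at least 3022 genes were called in either interaction after median centring. Of the calls as deposited, 3199 for sets 5 and 3 and 2113 for sets 6 and 3 kept call and direction. Without any 1 library the centred counts were 3932 to 4879 for sets 5 and 3 and 2215 to 3126 for sets 6 and 3. A technical difference between sets cannot be told apart from what the set numbers stand for, since each of the 3 sets has its own libraries.

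Most genes stood higher in KO cells of sets 5 and 6. The 99th percentile of the values was higher in KO cells by at least 0.34, close to the shift of the median (0.39 and 0.41). At the 10th percentile the shift was larger, 0.63 in set 5 and 0.65 in set 6, but it was also 0.40 in set 3, where the median shifted by -0.03. The rise was thus found at low and high levels and was not of 1 size. A scale difference kept by the authors' normalization and a rise of most transcripts in KO cells both predict this value of 0.34 and cannot be told apart without an outside measure of RNA amount. One scale factor as the whole cause of the calls was excluded, with 4669 or more genes called after centring (2929 or more with the call and direction of the deposited values), and 5119 to 6366 in set 5 and 3516 to 4810 in set 6 without any 1 library.

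Th2 cytokine genes are also made by mast cells and basophils, so RNA from such cells was weighed against a change of the T cells. In set 3 the median centred difference of 7 granulocyte and mast cell markers was 1.91 (95% bootstrap interval 1.31 to 4.31). For Th2 genes it was 2.72 (1.92 to 3.03). The markers' upper end was 1.22 in set 5 and 1.0 in set 6, below Th2 medians of 2.33 and 1.81. Markers went both ways there and only 2 of 7 had a WT mean of 6 or more. KO means of sets 5 and 6 were 1.87 and 2.25 for Mcpt8 but 4.08 and 5.08 for Cpa3, above WT. RNA from such cells stays open in all sets. Markers of 8 other cell types in set 3 had a median of 1.65 over 56 genes, against -0.15 to 0.17 for the middle 95% of 10000 random lists matched on level, 0 of which reached it. A general rise of weakly expressed genes was thereby excluded, and whether other cells or the T cells made these transcripts was not tested.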

How the results depend on the processing

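Minimum folds, the mean filter, the block within genotype and the average of sets 5 and 6 were chosen only after the results were seen. With a log2 difference of 1 or more, the calls were 607, 2234 and 1845 for KO against WT in sets 3, 5 and 6, 1217 for the mean over sets, 2466 and 1988 for the effects of sets 5 and 6 against set 3, 3785 and 4767 between sets 5 and 3 in WT and KO cells, and 171 and 264 between sets 6 and 5. A minimum fold of 1.2 gave 492, 4743, 4419 and 3522, then 3787 for sets 6 and 3, and 87 and 75 between sets 6 and 5. With centring and this minimum fold the counts were 513, 3046, 1763 and 2126, then 2270 and 1071 for the effects, and 64 and 46. Median centring gave 4669 in set 6, 3022 for sets 6 and 3, and 258 and 943 between sets 6 and 5, and quantile normalization 4723, 3076, 226 and 931. The compared groups alone gave 379 in set 3 and 643 and 519 between sets 6 and 5, and library weights 1239 between sets 6 and 5 in WT cells. With the estimated correlation 3, 0, 0 and 0 lists were shifted in sets 3, 5 and 6 and the mean.

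Leaving out 1 library gave 666 to 1914 calls in set 3, 6619 to 7154 in set 5, 6679 to 6903 in set 6 and 7693 to 7928 for the mean. For the effects it gave 5793 to 6363 (sets 5 and 3), 5739 to 6428 (6 and 3) and 0 to 1 (6 and 5). Between sets 5 and 3 it gave 7876 to 8186 in WT and 8765 to 8879 in KO cells, and between sets 6 and 5 113 to 385 and 589 to 1647. The shifted lists numbered 20 to 23, 11 to 12, 11 to 14 and 12 to 16. All other settings kept every count within 1.5 times.

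The replicate number as a block, which pairs sets 5 and 6, gave 740 calls between these sets in WT cells and changed no other count by over 1.5 times. Blocked within genotype, 11 genes differed in effect between sets 6 and 5. KO and WT libraries share only a number: the block gave 1316, 7302 and 7397 calls in sets 3, 5 and 6, and not every library correlated best with its own number. Of 2683 alternative values of 215 named results, 2638 kept direction and call, 41 lost the call, 4 gained it and 0 reversed. Tbx21 passed in sets 3 and 5 with the block (adjusted p = 0.04 and 0.0198), and Dapl1 in set 3 did not (0.0713). Fitting the compared groups alone leaves the mean over sets unchanged.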

Other observations

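The splits of libraries counted for called genes were chosen only after the calls were seen, while those counted for gene lists and the test of matched random lists were set before the data were examined. Single interferon response genes and regulators of cytokine signalling had another KO effect in set 5 than in set 3. Irf1, an activator of interferon-induced genes, rose by 1.96 (SE 0.14) and Irgm1, a GTPase against intracellular microbes, by 1.82 (SE 0.13), whereas in set 3 Irgm1 fell by 0.67 (SE 0.13) and Ifi47, a related GTPase, by 0.93 (SE 0.14). The interaction of sets 5 and 3 was 2.49 (SE 0.19; adjusted p = 4.41e-07) for Irgm1 and 2.36 (SE 0.20; adjusted p = 7.05e-07) for Irf1. Of 38 interferon-stimulated genes in set 5, 14 rose and 2 fell after centring, 22 and 1 as deposited and 23 and 1 adjusted over the list alone (adjusted p = 0.189). Of 26 cytokine receptor signalling regulators, 14 rose and 3 fell, 21 and 2 as deposited and adjusted over the list alone (adjusted p = 0.0338, 0.778 with an estimated correlation). Ifngr2, a chain of the interferon gamma receptor, rose by 3.33 (SE 0.41), Jak2 by 2.45 (SE 0.14) and the feedback inhibitor gene Socs1 by 1.43 (SE 0.19).

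In set 3, 5 of the 38 interferon-stimulated genes rose and 6 fell, or 7 and 13 adjusted over the list alone (adjusted p = 0.104). The 5 became 1 without KO replicate 3 or WT replicate 1, 2 without KO replicate 1 or WT replicate 2, and 8 without WT replicate 3. The regulators did not pass as a list in set 3 (adjusted p = 0.731). For the interaction of sets 5 and 3, the interferon list did not pass (adjusted p = 0.132), and the regulators passed with the preset correlation only (adjusted p = 0.0484, 0.608 with an estimated correlation).

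Stress response lists were shifted upward in sets 3 and 6 and did not pass in set 5. In set 5, 8 of 24 immediate early and heat shock genes rose and 1 fell, 15 and 1 as deposited and 16 and 1 adjusted over the list alone (adjusted p = 0.177). Of 23 unfolded protein response genes in set 5, 8 rose and 8 fell, 15 and 1 as deposited and adjusted over the list alone (adjusted p = 0.559), and 2 fell as deposited without KO replicate 2. In set 3, 8 of 24 immediate early and heat shock genes rose, or 9 adjusted over the list alone (adjusted p = 0.000139, 0.0953 with an estimated correlation). The 8 became 2 without KO replicate 1, 4 without KO replicate 3, 3 without WT replicate 1 and 5 without WT replicate 2. Of 23 unfolded protein response genes 5 rose in set 3, or 7 adjusted over the list alone (adjusted p = 1.88e-05, 0.102 with an estimated correlation), which became 1 without KO replicate 1 or WT replicate 3 and 3 without KO replicate 3. Of 19 p53 targets in set 3, 6 rose and 1 fell, or 8 and 1 adjusted over the list alone (adjusted p = 0.00146, 0.225 with an estimated correlation). The 6 became 3 without KO replicate 1 or WT replicate 3, and the 1 became 0 without KO replicate 1 and 3 without KO replicate 2. In set 6, 11 of 24 immediate early and heat shock genes rose and 1 fell, 19 and 1 as deposited and 21 and 1 adjusted over the list alone (adjusted p = 0.0104, 0.519 with an estimated correlation). Jun and Junb, genes of AP-1 transcription factors, rose by 1.55 (SE 0.18) and 1.27 (SE 0.11) in set 6. Of 23 unfolded protein response genes in set 6, 10 rose and 1 fell, 19 and 1 as deposited and adjusted over the list alone (adjusted p = 0.0269, 0.567 with an estimated correlation), a list call lost in 4 alternatives. The chaperone genes Dnajb9 and Hspa5 rose by 1.17 (SE 0.12) and 0.76 (SE 0.07) in set 6, and the 1 fall was lost without KO replicate 3 or WT replicate 1.

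Several lists of metabolic and growth genes stood lower in KO cells of sets 5 and 6 after centring. In set 5, 12 of 21 measured glycolysis entries fell and none rose, 4 as deposited and adjusted over the list alone (adjusted p = 0.000102, 0.744 with an estimated correlation), with the glucose transporter gene Slc2a3 falling by 1.02 (SE 0.25). Of 19 hypoxia response genes in set 5, 9 fell and 2 rose, 8 and 2 as deposited and adjusted over the list alone (adjusted p = 0.000265, 0.722 with an estimated correlation); the 8 became 4 without KO replicate 3. Vegfa, a growth factor gene of blood vessels, fell by 0.81 (SE 0.12), while Hif1a rose by 1.56 (SE 0.18). Of 28 ribosome biogenesis and Myc targets in set 5, 19 fell and 1 rose, 9 and 2 as deposited and 8 and 2 adjusted over the list alone (adjusted p = 0.000102, 0.744 with an estimated correlation), with Nop16 falling by 0.67 (SE 0.11). Replication-dependent histones fell in 10 of 19 cases in set 5, 3 as deposited and 2 adjusted over the list alone (adjusted p = 3.72e-05, 0.441 with an estimated correlation), and the 3 became 7 without KO replicate 2. Of 33 nuclear genes of oxidative phosphorylation in set 5, 29 fell and 2 rose, 7 and 8 as deposited and 6 and 8 adjusted over the list alone (adjusted p = 0.0018, 0.722 with an estimated correlation), and the 7 became 4 without KO replicate 3 or WT replicate 1. In set 3 the hypoxia list was shifted upward with 1 gene rising, also adjusted over the list alone (adjusted p = 0.0157, 0.484 with an estimated correlation), or 5 without KO replicate 2. No glycolysis or ribosome gene passed there (adjusted p of the lists 0.0801 and 0.267), but 2 glycolysis genes rose without KO replicate 2 and 1 without WT replicate 3. Oxidative phosphorylation was shifted downward in set 3 (adjusted p = 0.0358, 0.486 with an estimated correlation), a call lost in 6 alternatives, with 1 gene falling, none adjusted over the list alone, 2 without KO replicate 2 and 0 without any 1 other library. In set 6, 8 glycolysis entries fell, 3 as deposited and none adjusted over the list alone (adjusted p = 7.6e-05, 0.567 with an estimated correlation), and the 3 became 0 without KO replicate 3 and 1 without WT replicate 1. Of the hypoxia genes in set 6, 11 fell and 2 rose, 4 and 3 as deposited and adjusted over the list alone (adjusted p = 3.95e-05, 0.54 with an estimated correlation). The 4 became 8 without KO replicate 2 and 2 without KO replicate 3 or WT replicate 3. Of the ribosome genes in set 6, 13 fell and none rose, but 3 fell and 7 rose as deposited and adjusted over the list alone (adjusted p = 0.00505, 0.741 with an estimated correlation). The 3 became 1 without KO replicate 3 and the 7 became 4 without WT replicate 3. Of the oxidative phosphorylation genes in set 6, 24 fell and 2 rose after centring, but none fell and 16 rose as deposited, or 15 adjusted over the list alone (adjusted p = 0.824). Apoptosis regulators in set 6 and p53 targets in set 5 did not pass as lists (adjusted p = 0.871 and 0.559), while the survival gene Mcl1 rose by 1.06 (SE 0.12) in set 6 and Mdm2, which encodes the inhibitor of p53, by 0.75 (SE 0.06) in set 5. The 13 mitochondrially encoded genes had 3 falling and none rising in set 5, but none and 6 as deposited and adjusted over the list alone (adjusted p = 0.933).

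Other ways of dividing the libraries gave the following counts. For KO against WT within a set, and between sets within a genotype, only 10 divisions of 6 libraries exist, too few for a share under 0.05, and the real division alone gave as many genes as it did (1 of 10 each). The real counts and the highest of the others were 1427 and 277 in set 3, 7299 and 0 in set 5, 7336 and 1 in set 6, 8479 and 0 (WT) and 9180 and 2 (KO) between sets 5 and 3, and 423 and 0 (WT) and 1501 and 4 (KO) between sets 6 and 5. For the mean over sets, 1 of 100 divisions gave as many genes (7964, highest other 3631), and the same limits hold. For the interactions, regroupings of the residuals of a model without the interaction were used: 1 of 100 gave as many genes between sets 5 and 3 (6276, highest other 2729), 1 of 100 between sets 6 and 3 (6314, highest other 1806), and 100 of 100 between sets 6 and 5, where the real count was 0 (highest other 1).

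Counts of shifted gene lists did not stand out from other divisions. The 23 lists of set 3 were reached by 2 of 10 divisions (highest other 24), the 12 of set 5 by 2 of 10 (highest other 13), the 13 of set 6 by 1 of 10 (highest other 12) and the 12 of the mean over sets by 44 of 100 (highest other 20). Some list calls ended in single alternatives. With quantile normalization these were oxidative phosphorylation, NK markers and histones in set 3, Th1 and erythroid genes in set 5, and unfolded protein response, NK, granulocyte and mast cell, and histone genes in set 6. With the mean filter they were oxidative phosphorylation and the NK, B cell, erythroid, γδ and NKT, and granulocyte and mast cell markers in set 3, cytokine regulators and erythroid markers in set 5, and unfolded protein response, NK, and granulocyte and mast cell genes in set 6. With 1 library left out of set 3, calls ended for oxidative phosphorylation (KO replicate 1 or 3, WT replicate 1 or 3), NK markers (KO replicate 2, WT replicate 1 or 3), histones (KO replicate 2 or 3, WT replicate 3), hypoxia (KO replicate 3, WT replicate 1 or 2), regulatory T cell genes (KO replicate 1 or 3, WT replicate 1), and p53 targets and cholesterol synthesis (KO replicate 2). In set 5 they ended for Th1 (KO replicate 1), cytokine regulators (KO replicate 3) and erythroid genes (WT replicate 2). In set 6 they ended for unfolded protein response (KO replicate 2, WT replicate 3), NK markers (KO replicate 2, WT replicate 1 or 2, also with the replicate block), histones (KO replicate 3) and ribosome genes (WT replicate 1).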
